A study of Homo sapiens with 2 samples.

How the data were processed

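RNA of the SAS line, an established human tongue squamous cell carcinoma cell line, was measured on 2 two-colour microarrays, 1 for control cells and 1 for cells with a stable METTL3 knockdown, both harvested 24 h after adhesion. Cells were grown in medium with 10% serum and 1% antibiotics, per the labels' protocols. Per the labels, each RNA sample was divided into an immunoprecipitated part (IP, labelled with Cy5) and the remaining supernatant (Sup, labelled with Cy3), and the same amount of spike-in RNA went into each part before amplification and labelling. The labels do not state what the antibody bound. The reading of IP as RNA carrying m6A rests on the METTL3 design, since METTL3 is the catalytic subunit of the m6A writer. No dye swap is given in the labels, so a dye effect of a probe cancels only in the difference between the arrays.

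The deposited values are fluorescence intensity per spot, extracted by the authors with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. Each deposited file holds 62976 spots with the background-subtracted intensity, a dye-normalized intensity and spot flags. The background-subtracted intensity was the starting point here. A total of 1002 spots carrying a flag for saturation, non-uniformity or a replicate outlier in any channel of either array were dropped. Each channel was floored at the 95th percentile of its negative control spots. Channels were then scaled so that the mean log2 intensity of 24 spike-in probes was equal in all 4 channels. These 24 were the probes well above background in all channels among 114 whose names mark them as spike-ins. That identity was read from the probe names and rests on no annotation.

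The following quantities were computed per spot and averaged over the good spots of a probe: the total (IP plus Sup, linear scale, then log2), the IP signal, log2(IP/Sup), and the IP share, which is IP as a percentage of IP plus Sup. Probes well above background in any channel counted as measured for abundance and IP signal (42181 probes), and those well above background in all 4 channels as measured for the ratio (31757 probes). A difference is knockdown minus control. With 1 array per group no test between groups exists and no p-value is given. Errors of single genes are the SE or SD over replicate spots of the same array, which leaves out variation between cultures and between hybridizations. The SE of the spike-in mean gives the intervals of array-wide medians (1.96 SE). The number of arrays limits the precision.

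Gene symbols were taken for 50 probes that carry a RefSeq accession, all 50 of which matched the reference table of names, and for 4 control probes named for human GAPDH and PGK1. The files do not pair the other 60511 probes with genes, so array-wide counts are counts of probes, not of genes. The planned analyses of genes used probes as their unit for this reason. METTL3 and the other genes of the m6A machinery are not analysed here. Of 34 gene lists fixed before the data were examined, 6 had any member with a symbol and none reached 5, the minimum for a percentile, so members are given as values. Ratios by transcript class and feature are not analysed here. The array grid and the name table use different genome builds, so no coordinates are given.

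The named-gene rule took, for each quantity, the 10 highest and 10 lowest differences among symbol-bearing genes well above background in all channels, with a mean total above the median of measured probes and other probes differing in the same direction, and then members of the fixed lists. Because nearly all panel genes were above 0 after spike-in scaling, the lowest-ranked ones include values above 0. Genes outside that rule were named only where stated. Alternatives were other scalings, signal columns, filters, low-value treatment, thresholds and spike-in subsets.

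The computation was tested on simulated data in 20 draws with noise taken from replicate spots. A true shift of 0.50 in all transcripts came back as a median of 0.49 (range 0.44 to 0.54), and a true ratio shift of 0 as -0.03 (range -0.12 to 0.07). Of probes changed 3-fold in total, 98.0% were found at least 2-fold different, and 99.8% of those changed 4-fold. For the ratio these shares were 90.8% and 96.5%. Among unchanged probes, 0.180% passed 2-fold in total and 3.78% in the ratio. The simulated noise leaves out variation of single probes between hybridizations, so these shares are not error rates for the 2 arrays. In the data the total difference had an SD of 0.57 over spike-in probes. All these calls were made relative to the median recovered in each draw. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.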

Results

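Control SAS cells and SAS cells with a stable METTL3 knockdown were compared on 1 array each, so no difference below has a replicate check. In the control array, 63.4% of transcript spots were well above background in the Sup channel and 57.6% in the IP channel. In the knockdown array these shares were 63.3% and 67.0%. The median background-subtracted intensity was 11.2 (Sup) and 11.8 (IP) in the control array, against 11.5 (Sup) and 25.1 (IP) in the knockdown array. Across the 31757 probes measured in all channels, which are not independent replicates, the arrays had a Spearman rho of 0.95 for the total and 0.87 for the IP/Sup ratio. METTL3 itself is not analysed here, so the knockdown was not checked on these arrays.

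The first comparison asked which transcripts differed in abundance between knockdown and control cells. Among 42 panel genes well above background in all channels, NMI, which encodes an interactor of MYC and STAT proteins, had the highest difference, with a total 3.88-fold that of the control (log2 difference 1.96 ± 0.03, SE over spots). ZZZ3, a subunit of a histone acetyltransferase complex, was 3.41-fold (1.77 ± 0.08). MTDH, which encodes metadherin, was 3.13-fold (1.65 ± 0.09), and RND3 was 3.12-fold (1.64 ± 0.08). The lowest values belonged to POLR2A, the largest subunit of RNA polymerase II (-0.21 ± 0.09), and ABRAXAS1, a scaffold of a BRCA1 complex (-0.14 ± 0.05). On the spike-in scale POLR2A turned positive with the ERCC-named spike-in probe alone, and ABRAXAS1 with that probe and with the median of the spike-in probes.

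These values sit on a shift of the whole array. The median log2 difference in total over 42181 probes was 0.54 (interval from the spike-in SE 0.31 to 0.77), which is 1.45-fold. The interval does not cover the choice of spike-in scaling. With the median of the spike-in probes the value was 0.82, and with the ERCC-named probe alone 1.02. Before scaling, the spike-in probes differed by a mean of -0.45 in Sup and 0.60 in IP. Relative to the array median of 0.54, NMI was 2.68-fold higher (1.42), ZZZ3 2.35-fold (1.23), MTDH 2.16-fold (1.11) and RND3 2.15-fold (1.11). Those 4 were the panel genes at least 2-fold higher, and 0 of the 42 were 2-fold lower. The number higher was 7 without background subtraction and with an offset, and 3 under quantile normalization. It was 5 with the median of the spike-in probes and with the ERCC-named probe alone. POLR2A was at -0.75 relative to the array, ABRAXAS1 at -0.68, RHOH at -0.46, and PLA2G4A, a cytosolic phospholipase, at -0.43. The RHOH probe was bright (total signal 16035 in the control array) and rested on 5 spots. Probes in the brightest of 6 classes had a median total difference of only 0.32 after spike-in scaling. Each of these 8 genes lay on the same side of the array median under all 10 alternatives. The difference from the array median exceeded 2 SE of the spots in 34 of the 42 genes. The SD of the total difference was 0.47 over panel genes and 0.57 over the 24 spike-in probes (95% interval of the latter 0.45 to 0.81), so panel genes did not differ among themselves by more than the spike-in RNA did.

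**Figure D1:**
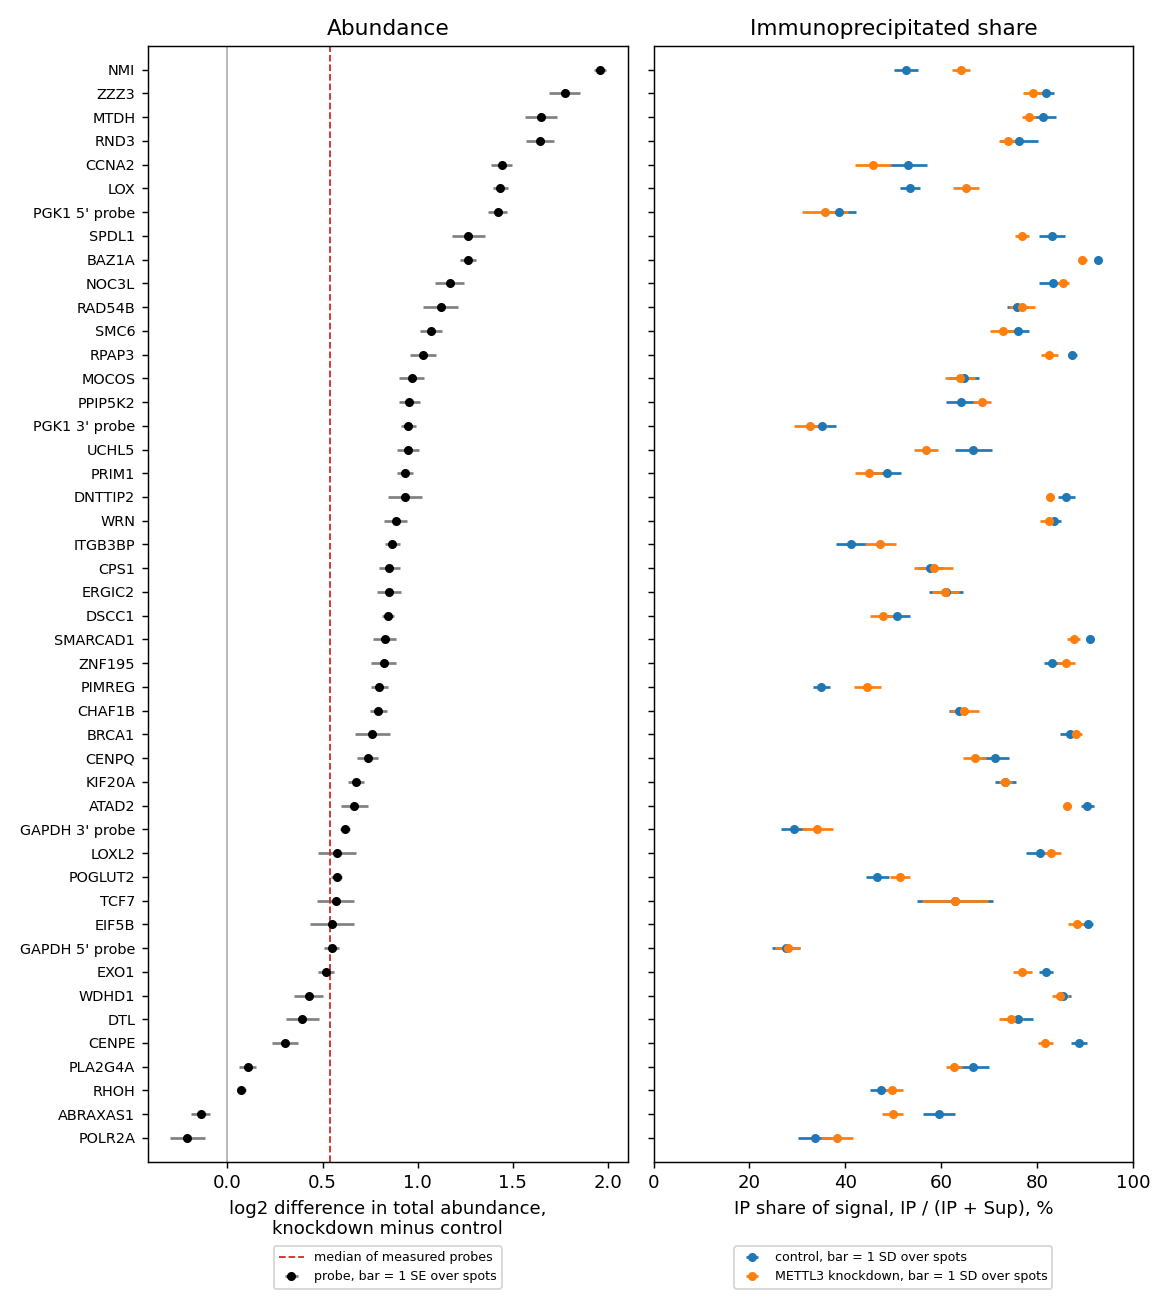
Named genes well above background in all channels. Left, log2 difference in total abundance (knockdown minus control) with 1 SE over replicate spots, where the dashed line is the median of measured probes at 0.54; right, IP share in percent in each array with 1 SD over spots. NMI sits highest at 1.96 and POLR2A lowest at -0.21.

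By fixed list, the G2/M genes were CCNA2, KIF20A and CENPE. CCNA2, which encodes a cyclin, was at 1.44 ± 0.06 (0.90 relative to the array), KIF20A, a mitotic kinesin, at 0.68 ± 0.04 (0.14) and CENPE, a kinetochore kinesin, at 0.30 ± 0.07 (-0.24). The signs relative to the array turned for KIF20A under quantile normalization and for CENPE without background subtraction, with an offset and with the median of the spike-in probes. The mesenchymal list had LOX, a collagen cross-linking enzyme, at 1.43 ± 0.04 (0.90). DNA repair was represented by BRCA1 at 0.76 ± 0.09 (0.22) and EXO1, an exonuclease, at 0.52 ± 0.04 (-0.02), the latter changing sign under 4 alternatives. ZNF195, of the zinc finger list, was at 0.82 ± 0.07 (0.28), and TCF7, a WNT pathway transcription factor, at 0.57 ± 0.10 (0.03, with the other sign under 3 alternatives). TCF7 had a weak total signal, 18.4 in the control and 27.3 in the knockdown array, below the median of measured probes. The glycolytic housekeeping genes were at 0.62 ± 0.03 (GAPDH 3′ probe), 0.55 ± 0.04 (GAPDH 5′ probe), 0.95 ± 0.04 (PGK1 3′ probe) and 1.42 ± 0.05 (PGK1 5′ probe). Relative to the array, the GAPDH probes were within 0.08 of 0 and changed sign under 1 (3′) and 3 (5′) alternatives. The PGK1 probes were at 0.41 (3′) and 0.88 (5′) relative to the array, above 0 under all 10 alternatives. The 3′ to 5′ signal ratio of GAPDH was 3.36 in Sup and 3.64 in IP of the control array, and 3.30 and 4.40 in the knockdown array. For PGK1 it was 101 and 86.9 in the control array and 72.3 and 63.1 in the knockdown array.

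Over the whole array, 10847 probes were at least 2-fold higher in total and 630 at least 2-fold lower after spike-in scaling. Relative to the array median the split was 3039 higher and 2863 lower, and with each channel scaled to its median it was 2148 higher and 3393 lower. Quantile normalization gave 3620 higher and 2210 lower. The size of the split depended on the scaling, and its direction turned with median scaling of each channel.

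The second comparison concerned the quantity of immunoprecipitated RNA. NMI again ranked first in the panel, with an IP signal difference of 2.24 ± 0.05, followed by ZZZ3 at 1.73. LOX followed at 1.72 ± 0.07. ABRAXAS1 was lowest at -0.40, then POLR2A at -0.02 ± 0.14. ABRAXAS1 turned positive with the median of the spike-in probes and with the ERCC-named probe alone, and POLR2A with both of these, with the 12 brighter spike-in probes, without background subtraction and with an offset. IP signal was above 0 for 40 of the 42 genes. The array median was 0.61 (0.35 to 0.87), with 13420 probes at least 2-fold higher and 1116 lower. Relative to that median there were 4773 and 4380, under median scaling of each channel 4148 and 5083, and under quantile normalization 7682 and 3462.

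The third comparison asked whether transcripts had a smaller immunoprecipitated share when METTL3 was lowered. The IP share was lower in the knockdown for CENPE, at 88.7% in the control array and 81.6% in the knockdown array (log2 ratio difference -0.83 ± 0.11). ATAD2, a chromatin-binding ATPase, was at 90.4% and 86.1% (-0.62 ± 0.08), UCHL5, a proteasome-associated deubiquitinase, at 66.7% and 56.8% (-0.61 ± 0.10), SPDL1, a kinetochore protein, at 83.0% and 76.8% (-0.58 ± 0.12), and ABRAXAS1 at 59.5% and 49.8% (-0.57 ± 0.09). BAZ1A, a chromatin remodelling subunit, was at 92.6% and 89.4%. Spike-in probes with control log2 ratios of 1.75 to 3.67 also had lower ratios in the knockdown array (-0.49 to -1.53). Over all 24 spike-in probes the ratio difference fell with the control ratio (slope -0.28 ± 0.04). The falls of CENPE, ATAD2, SPDL1 and BAZ1A therefore cannot be told apart from an effect shared with the spike-in RNA. UCHL5 and ABRAXAS1 had lower control shares, and for them the spike-in probes do not settle this. Spike-in probes with control log2 ratios of 0.39 to 0.83 had ratio differences in both directions (-0.33 to 0.55). The share was higher in the knockdown for LOX, at 53.5% and 65.1% (0.70 ± 0.08), for NMI, at 52.7% and 64.1% (0.68 ± 0.07), and for PIMREG, a mitotic regulator, at 35.0% and 44.6% (0.58 ± 0.08). Relative to the array median each of these 9 genes kept its direction under all 10 alternatives. On the spike-in scale, the differences of ABRAXAS1, BAZ1A and SPDL1 turned positive when the median of the spike-in probes replaced their mean. None of the 42 differed 2-fold in the ratio scaled by the mean of the spike-in probes. The median of the spike-in probes raised the panel's median ratio difference from -0.12 to 0.47. Under it LOX, NMI and PIMREG passed 2-fold.

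GAPDH had a share of 29.2% in the control and 34.2% in the knockdown array at its 3′ probe (log2 ratio difference 0.33 ± 0.10), and 27.6% and 28.0% at its 5′ probe (0.03 ± 0.11). PGK1 was at 35.1% and 32.7% at its 3′ probe and at 38.6% and 35.8% at its 5′ probe. Of the 42 panel genes, 19 had a lower ratio and 8 a higher ratio by more than 2 SE of the spots under the mean spike-in scaling. The number of these genes with a ratio difference above 0 was 17 under that scaling, 39 with the median of the spike-in probes and 6 with the authors' dye-normalized signal. The SD of the ratio difference was 0.37 over panel genes and 0.48 over spike-in probes (interval 0.37 to 0.67).

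Across all 31757 probes the median share was 54.4% in the control and 56.2% in the knockdown array. The median log2 ratio difference was 0.13, with an interval of -0.06 to 0.32 that includes 0, so no array-wide decrease in the IP share was detectable. With the median of the spike-in probes in place of their mean, this median was 0.72. It was -0.04 with the authors' dye-normalized signal, -0.008 under quantile normalization and -0.004 without the background filter. Median scaling of each channel, which sets it near 0 by construction, gave 0.002. The other alternatives gave 0.11 to 0.17. At least 2-fold differences were found for 1279 probes upward and 881 downward, against 758 and 1310 relative to the array median. In the simulated arrays, 3.78% of probes without a true ratio difference passed this threshold relative to the array median from spot noise. That share counts both directions together. In the data, relative to the array median, 2.39% of probes were higher and 4.13% lower, which together exceed the simulated share.

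**Figure D2:**
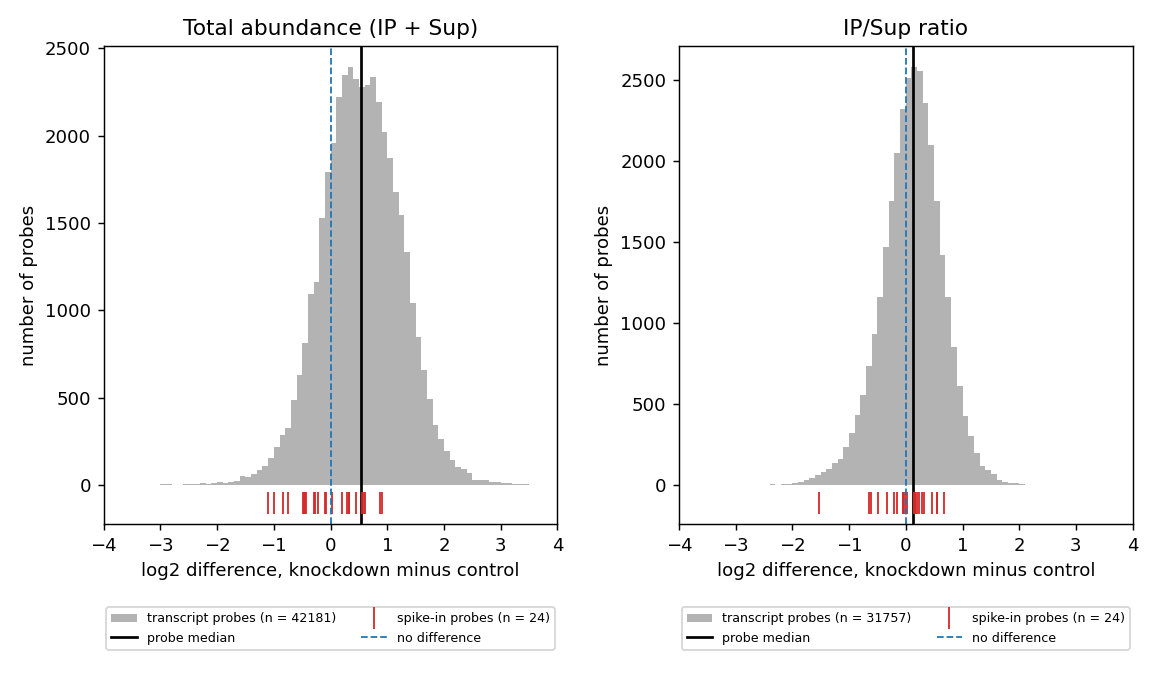
Distribution of log2 differences (knockdown minus control) over transcript probes for the total (left) and the IP/Sup ratio (right), with spike-in probes as red ticks. The probe medians lie at 0.54 and 0.13, inside the range of the 24 spike-in probes.

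The last comparisons asked whether abundance differences followed the immunoprecipitated share. The control IP/Sup ratio and the total difference had a Spearman rho of 0.15 across 31757 probes. Simulated arrays without a true relation gave -0.14 (range -0.21 to -0.05). The observed value was 0.076 under quantile normalization. Over the 42 panel genes it was 0.064 with all spots and 0.070 with different spots. Levels of the ratio across probes need not reflect the immunoprecipitated share. The SD of the control log2 ratio was 1.38 over spike-in probes and no larger over transcript probes. The spike-in RNA was added equally to both parts, if the probe names identify it. The median total difference was 0.24 in the lowest of 5 equal classes of the control ratio (median share 31.0%) and 0.65 in the highest (76.0%). Without the background filter rho was -0.033, and by brightness class it ran from -0.09 in the dimmest to 0.43 in the brightest. The ratio difference and the total difference had a rho of 0.27. Spot noise alone gave 0.49 (range 0.47 to 0.51) in simulated arrays without a true relation, because the same signals enter both values. Over the 42 panel genes rho was 0.011 with all spots and -0.018 with ratio and total taken from different spots.

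**Figure D3:**
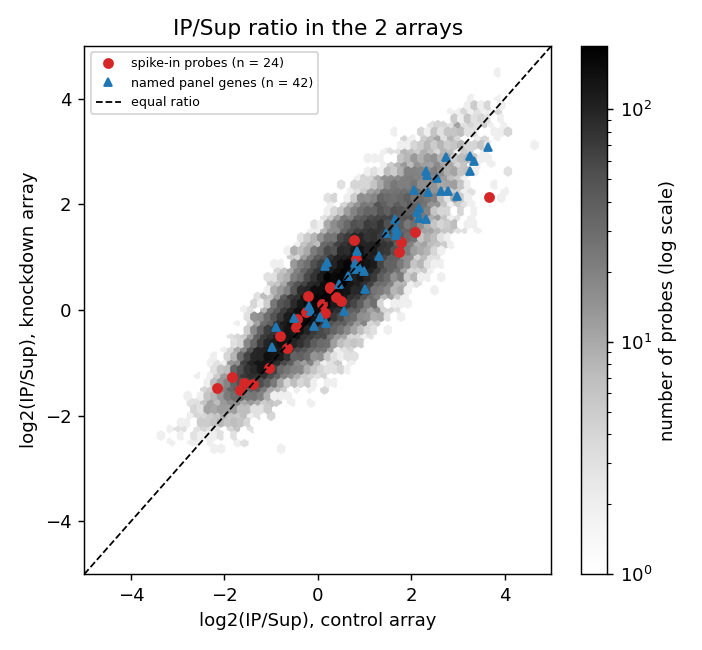
log2(IP/Sup) of each probe in the control array (horizontal) and in the knockdown array (vertical), with shading for the number of transcript probes, red points for the 24 spike-in probes and blue triangles for the 42 panel genes. Spike-in probes with high control ratios lie below the line of equal ratio.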

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

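The test of the slope of the ratio difference on different spots was fixed before its result was seen, and the other tests below were chosen after related values had been seen.

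A set of 7 control probes named for other species or for no added RNA were well above background in all channels. In the control Sup channel, whose floor was 1.22, the intensity was 2603 for the rat GAPDH 5′ probe, 52.2 and 14.6 for the mouse GAPDH 3′ and 5′ probes, 34.8 and 15.4 for the mouse PGK1 3′ and 5′ probes, 26.5 for the rat PGK1 5′ probe, and 31.8 for the control probe ETG05_66023.

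After spike-in scaling, totals were higher across the array in the knockdown, unevenly by brightness. Background in weak spots is argued against as the whole cause by the brightest of 4 equal classes of measured probes, with a median of 0.50, and by the brightest of 6 classes of the probes detected in all channels, with 0.32, both above 0 by more than the spike-in half-width of 0.23. The choice of spike-in probes stays open, since 18 of 24 used alone gave a median above 0 and the others did not, although the interval around the mean-scaled median (0.31 to 0.77) excluded 0. An unequal amount of RNA or spike-in and a higher RNA content of knockdown cells cannot be told apart. The spike-in RNA went into the parts of an RNA sample, not into the cells, and each group has 1 array. Both explanations predict a shift of one sign, and the lowest median was 0.48 over the 4 classes. The 6 classes ran from 0.31 in the dimmest to 0.71 in the second brightest and 0.32 in the brightest, all of one sign. The cause of this unevenness was not tested.

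The range of IP/Sup ratios was narrower in the knockdown array. Noise between spots is argued against as the whole cause by the slope of the ratio difference on the control ratio taken from different spots of panel genes, -0.17 ± 0.04 (SE), but in simulated arrays it alone gave -0.09 over transcript probes, part of the -0.16 observed there. An effect shared with the spike-in RNA is consistent with the slope of -0.28 ± 0.04 over spike-in probes. Whether a lower IP share of transcripts with a high control share in knockdown cells adds to that effect cannot be decided here. Levels of the ratio need not reflect the immunoprecipitated share, and noise between spots was not removed from either control-ratio slope. On the control ratio the slope over transcripts was -0.16, less steep than over spike-ins by 0.12 ± 0.04. On the mean of both ratios it was -0.04 against -0.29 ± 0.06. A lower IP share of transcripts with a high control share predicted a steeper slope over transcripts than over spike-ins. Both gaps exceeded 2 SE in the other direction. Without the most influential spike-in probe the gaps were 0.05 ± 0.05 and 0.16 ± 0.06, so the control-ratio gap rests on that probe. A looser bound, a resampled interval of the spike-in slope, was tried after the result had been seen. The bound of 2 SE was restored later. On the control ratio the resampled interval was -0.35 to -0.13 and held the transcript slope. On the mean of both ratios it was -0.41 to -0.08 and did not hold the transcript slope. Without the most influential probe that interval was -0.31 to -0.03 and held it.

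Panel genes differed in abundance relative to the array. Noise between spots is argued against, since 81.0% of the 42 genes lay more than 2 SE of their spots from the array median. Variation of single probes between arrays may account for the spread, as the SD was 0.47 over panel genes and 0.57 over spike-in probes. An effect of METTL3 loss stays open, because 1 array per group leaves no measure of variation between cultures.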

How the results depend on the processing

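No paired analysis was possible because each group has 1 sample, and for the same reason there was no replicate to leave out. The alternatives on spike-in subsets, on different spots and within brightness classes were chosen after seeing the data. Alternatives fixed before the data were examined that need several probes per gene, protein-coding labels or gene lists of at least 5 members were not run. Values are counts of probes at least 2-fold higher and lower unless stated, and the cause of each move was not tested beyond the construction of the alternative.

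With each channel scaled to its median, which sets channel medians equal by construction, the median difference was -0.087 in total and -0.073 in IP signal, with 2148 and 3393 probes (total), 4148 and 5083 (IP signal) and 763 higher in the ratio. Quantile normalization gave medians of 0.075 in total and 0.16 in IP signal, with 3620 and 2210 probes (total) and 7682 and 3462 (IP signal). The authors' dye-normalized signal gave 741 higher in the ratio. Without background subtraction the counts were 5964 and 137 (total), 7774 and 148 (IP signal), and 823 and 247 (ratio). Without the background filter they were 1682 lower in IP signal and 4507 and 3898 in the ratio, and the rho of the control ratio with the total difference was -0.033. The stricter filter, which leaves fewer probes, gave 6507 and 228 (total), 7699 and 305 (IP signal) and 355 lower in the ratio. An offset of 16 in place of the floor gave 5637 and 132 (total), 7739 and 162 (IP signal) and 226 lower in the ratio, with a median IP difference of 0.34 and a rho of ratio difference with total difference of 0.37. At a 1.5-fold threshold the counts were 20041 and 2031 (total), 21551 and 2933 (IP signal), and 5566 and 3050 (ratio). At 4-fold they were 774 and 59, 2099 and 114, and 12 and 16.

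The median of the spike-in probes in place of their mean moved the array-wide medians to 0.82 (total), 1.22 (IP signal) and 0.72 (ratio), with 16796 and 253, 25678 and 251, and 8911 and 119 probes, and a rho of the control ratio with the total difference of 0.29. The 12 brighter spike-in probes gave 735 lower in IP signal. The 1 detected ERCC-named spike-in probe alone gave medians of 1.02 (total) and 1.06 (IP signal), 21490 and 255 probes (total), 22299 and 390 (IP signal), and a rho of ratio difference with total difference of 0.39. Over the 42 panel genes that rho was -0.018 with different spots and 0.011 with all spots, so the gene set differs from the array-wide value as well. Of 2100 gene-level values over 35 named probes, 1535 moved by less than the SD of the spots, 565 moved by more, and no value of at least 2-fold changed sign. Signal over background limits what was measured: of 60561 transcript probes, 42181 entered the abundance counts and 31757 the ratio.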

Other observations

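The panel's median immunoprecipitated share was 74.6% in the control and 73.1% in the knockdown array. Dye and hybridization effects of single probes do not cancel in such levels. Spike-in probes had control log2 ratios from -2.15 to 3.67, though their RNA, if the probe names identify it, was added equally to both parts. Against 10000 random sets of 42 probes matched on signal, the panel's median total difference of 0.85 lay at the upper edge of the range that held 95% of the sets (0.25 to 0.85), and its median ratio difference of -0.12 lay below the range (0.04 to 0.34). The panel's median control log2 ratio of 1.56 was outside these sets as well (-0.70 to 0.33). With sets matched on signal and on the mean of both ratios, the total difference was inside the range (0.61 to 1.04) and the ratio difference below it (0.02 to 0.39), while the control ratio was still above (1.06 to 1.52). Relative to the array median, the panel's median ratio difference was -0.25, and -0.01 with an offset in place of the floor. These comparisons describe the 2 arrays and were chosen after the panel values had been seen. The 42 panel probes shared a probe-name family that held no other probe measured for the ratio. A difference between probe families therefore cannot be told apart from a difference between genes here.

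By brightness class, the median ratio difference was -0.10 in the dimmest and 0.22 in the brightest of 6 classes of probes. The median control share was 60.2% in the dimmest class and 39.1% in the brightest.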
